A study of Halobacterium salinarum NRC-1 with 32 samples.

How the data were processed

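The arrays measured transcript levels in the halophilic archaeon Halobacterium salinarum NRC-1 during recovery from ethyl methanesulfonate (EMS), an alkylating chemical that damages DNA. Per the labels, mid-log cells in complex medium were held for 30 min with 100 mM EMS or, as a mock treatment, without it, then spun down, resuspended in fresh medium and left to recover at 37 °C. One RNA sample per treatment was taken at each of 8 times (0, 10, 20, 30, 40, 50, 60 and 120 min), which gives 8 EMS and 8 mock samples. Per the labels' protocols, DNA-free total RNA was checked by PCR for DNA, on a Bioanalyzer for integrity and in a spectrophotometer for amount. Each RNA was hybridised against a common mid-log reference RNA on 2 arrays with the dyes exchanged, Alexa 546 and Alexa 647, so that 32 arrays carry 16 RNA samples. The labels do not say whether the samples came from separate cultures, so every p-value below measures only the spread between time points, which may be technical.

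The deposited scanner files hold, per the file headers, the median intensity of each spot and of its local background in both dyes, each in an H and an L scan. These are called the high-gain and low-gain scans here, because the H values were the larger. The spot-finding software and its version are not given in the sources used here. The authors' table of values holds a log10 ratio for each spot and array. Set against the scanner values, its columns lay along log10 of Alexa 546 over Alexa 647 on arrays of both orientations, so the ratios were not turned for the dye exchange. Its column medians ran from 0.051 to 0.145. Its normalization and centring remain unknown. The number of value columns left unused was 0.

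Spots were matched to the value table by their place in the scanned image. With that order, scanner and table log ratios correlated across spots with r from 0.626 to 0.985 per array, against 0.056 to 0.250 in the order of the scanner files. Each table column correlated best with the scanner ratios of its own array for 29 of 32 arrays. Each probe had 4 spots. After 288 empty or control probes were left out, 2400 gene probes remained. The table of probe names used here gave 1 gene symbol to 133 of them. The other 2267 had no symbol or an entry with several, which was not used, and these cases were not counted apart. Those probes are called unnamed and are reported by the number of their first spot. Genome positions were not used here.

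Log ratios were computed from the scanner intensity values. Where a spot was saturated in the high-gain scan (65000 or more), its low-gain value was used, multiplied by the array's median high-over-low ratio of spots between 20000 and 60000. Background was corrected by normexp with an offset of 50, and each array was normalized by loess with empty and control spots at weight 0. Every ratio was turned to sample over reference, the spots of a probe were averaged, and the 2 arrays of 1 RNA were averaged and counted as 1 replicate. Values are log2 ratios of sample over reference. R 4.3.3 was used with limma 3.58.1 and version 1.17.8 of data.table, with Python 3.11.15 and matplotlib 3.10.9 for the plots.

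A probe was tested when, in both dyes, at least 50% of its spots were brighter than their local background on at least 17 of the 32 arrays, which left 955 probes, 78 of them named. Alexa 546 set this limit. On single arrays 21.5 to 64.2% of gene probes were above background in Alexa 546, against 73.9 to 92.7% in Alexa 647, and 55 named genes were too dim to be tested. With 8 RNA samples per treatment, the median standard error of an EMS minus mock difference over all times was 0.08 on the log2 scale. The rule for dim probes was chosen on the correlation, across probes, of the 2 arrays of each RNA, after these files were seen and before any treatment comparison. Its median over the 16 samples was 0.494 with this rule, 0.130 over the 1744 probes kept by an Alexa 647 limit set from empty positions, and -0.141 over all 2400. Arrays of the same dye orientation correlated across probes with r of at least 0.383. The number of array pairs with identical values was 0.

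The groups, tests, fixed gene lists, rule for named genes and first set of alternatives were written before the data were examined. EMS and mock were compared with limma (lmFit and eBayes, two-sided), with time point as a block of 8 levels because the labels match the treatments by time. A fit with separate EMS minus mock terms for 0 to 30 min and 40 to 120 min, 4 time points each, tested both windows and the change between them. Another fit of 4 cells, treatment by window, tested 40 to 120 min against 0 to 30 min within mock and within EMS. A probe passed at a Benjamini-Hochberg adjusted p under 0.05 over the 955 probes. Gene lists with at least 3 tested genes were tested with camera at its preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. Of 25 fixed lists, 16 held a named gene and 9 held none. A further 7 lists were written once gene names and array-level values, but no treatment comparison, had been seen. Together, 7 fixed and 3 added lists were large enough to test. The comparison of the windows over both treatments together and the tests of lists in the early and late windows were added after the data were seen.

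The named genes were, for EMS against mock, the 12 largest rises and 12 largest falls that passed with the same sign at 7 or more of 8 time points. They were the 8 largest changes each way for the change between windows, the 5 largest each way for each time course, and the up to 4 members of each fixed list with the smallest p. Values for all genes of the DNA repair lists were always to be given. The rule was applied among named genes too, and at most 2 unnamed probes are printed per direction. Both of these points were set once the gene names were seen.

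Alternatives replaced the background correction, the loess step, the scaling between arrays, the filter, the averaging of spots, the dye averaging, the sample weights and the form of the time term. The authors' value table and each time point left out in turn were also tried. The scan gain, a filter on Alexa 647, the value table's first print set, time points 0 to 40 min, the omission of 1 mock sample, the test of lists in each dye orientation and a term for groups of arrays were added after the data were seen. The arrays fall into such groups by the number of spots without a value in the authors' table: 841 on 27 arrays, 11 EMS and 16 mock, and 755 on 5 EMS arrays. The 16 mock arrays carry lower array numbers than every EMS array, and within each treatment the numbers follow time, so treatment and time cannot be separated from array order. The 5 are both arrays of EMS 60 and 120 min and the Alexa 647 array of EMS 50 min.

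The tests were checked on simulated data with 955 probes of which 200 were changed. For EMS against mock over all times, 51.6% of changes of 0.25, 89.9% of 0.5 and 100% of 1 on the log2 scale were recovered. For the change between windows, 5.17%, 58.8% and 86.5% of changes of these sizes were recovered. Over all times 165 probes passed in the simulation, against 20 in the data. The adjusted threshold is stricter when fewer probes change, and the simulated noise was independent between probes. Recovery in the data may therefore be lower than these shares.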

Results

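The arrays compared RNA of Halobacterium salinarum NRC-1 taken during recovery from 30 min in 100 mM EMS, an alkylating DNA-damaging chemical, with RNA taken at the same times after a mock treatment. There was 1 RNA sample per treatment at 0, 10, 20, 30, 40, 50, 60 and 120 min, so each group held 8 samples. Each sample was measured on 2 dye-exchanged arrays against a common mid-log reference, and the mean of the pair counted as 1 value. Values are log2 ratios of sample over reference, and errors are standard errors (SE) or standard deviations (SD) over time points. On single arrays, 21.5 to 64.2% of gene probes were above background in Alexa 546 and 73.9 to 92.7% in Alexa 647, and 60 to 174 probes were saturated in the high-gain scan. The tests covered 955 probes, of which 78 carried a gene name.

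The comparison over all 8 time points asked which transcripts stood at another level after EMS than after mock treatment. The transcript of gdhA1, a glutamate dehydrogenase that interconverts glutamate and 2-oxoglutarate, was lower after EMS by -0.36 ± 0.07 (SE), which is 0.78-fold. It averaged -0.43 ± 0.32 (SD, n = 8) in EMS and -0.07 ± 0.25 (SD, n = 8) in mock and was lower in EMS at 8 of 8 time points (limma, adjusted p = 0.0152). The transcript of dpsA, an iron-storing ferritin-like protein of the Dps family that protects against oxidative damage, was higher after EMS by 0.33 ± 0.06 (SE), which is 1.25-fold. It averaged -0.06 ± 0.17 (SD, n = 8) in EMS and -0.38 ± 0.13 (SD, n = 8) in mock and was higher at 8 of 8 time points (limma, adjusted p = 0.0246). The dpsA difference was 0.01 at 120 min, thus near none, and 0.22 to 0.45 at the other times. In all, 20 probes differed, 15 higher and 5 lower in EMS, with a median difference of 0.41 in size. The other 18 had no gene name here. With the sample in Alexa 546 alone and in Alexa 647 alone, gdhA1 stood at -0.34 (adjusted p = 0.0846) and -0.38 (adjusted p = 0.153), and dpsA at 0.17 (adjusted p = 0.298) and 0.48 (adjusted p = 0.0328). Of the 20 probes 19 had the same sign in both orientations. Over all 955 the differences of the orientations correlated with r = 0.206 and 55.1% had the same sign, so the smaller differences below rest on means of arrays that often disagreed. The largest of these were probe 4155 at +0.78 ± 0.17 (SE) and probe 2447 at +0.63 ± 0.10 (SE) among those higher. Among those lower they were probe 493 at -0.42 ± 0.07 (SE) and probe 253 at -0.31 ± 0.07 (SE). At an unadjusted p under 0.05 there were 146 probes, where 47.8 are expected by chance. With the group of arrays, set by spots without a value in the authors' table, as a covariate 3 probes passed, and within the first group, 0 to 40 min, 0 passed. The estimates of the 20 probes with the covariate kept their sign in 20 and came to a median of 0.967 times, and their errors to 1.25 times, those without it. With that covariate gdhA1 stood at -0.35 ± 0.09 (SE, adjusted p = 0.0890) and dpsA at 0.37 ± 0.08 (SE, adjusted p = 0.0630). Over 26 alternatives the call of gdhA1 held in 14 and that of dpsA in 10. The count was 11 without 10 min, 5 without 30, 50 or 60 min, 6 without 40 min and 34 without 20 min. Among the other alternatives it ran from 5 with no time block to 72 with sample weights. The gdhA1 call was lost without 30, 40, 50 or 60 min and the dpsA call without 10, 30, 40, 50 or 60 min, at differences from -0.36 to -0.33 and from 0.31 to 0.32. Spots of dpsA were saturated in the high-gain scan on all 32 arrays, and its difference was 0.00 ± 0.06 (SE) from the high-gain scan alone and 0.20 ± 0.09 (SE, adjusted p = 0.351) from the low-gain scan alone.

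**Figure D1:**
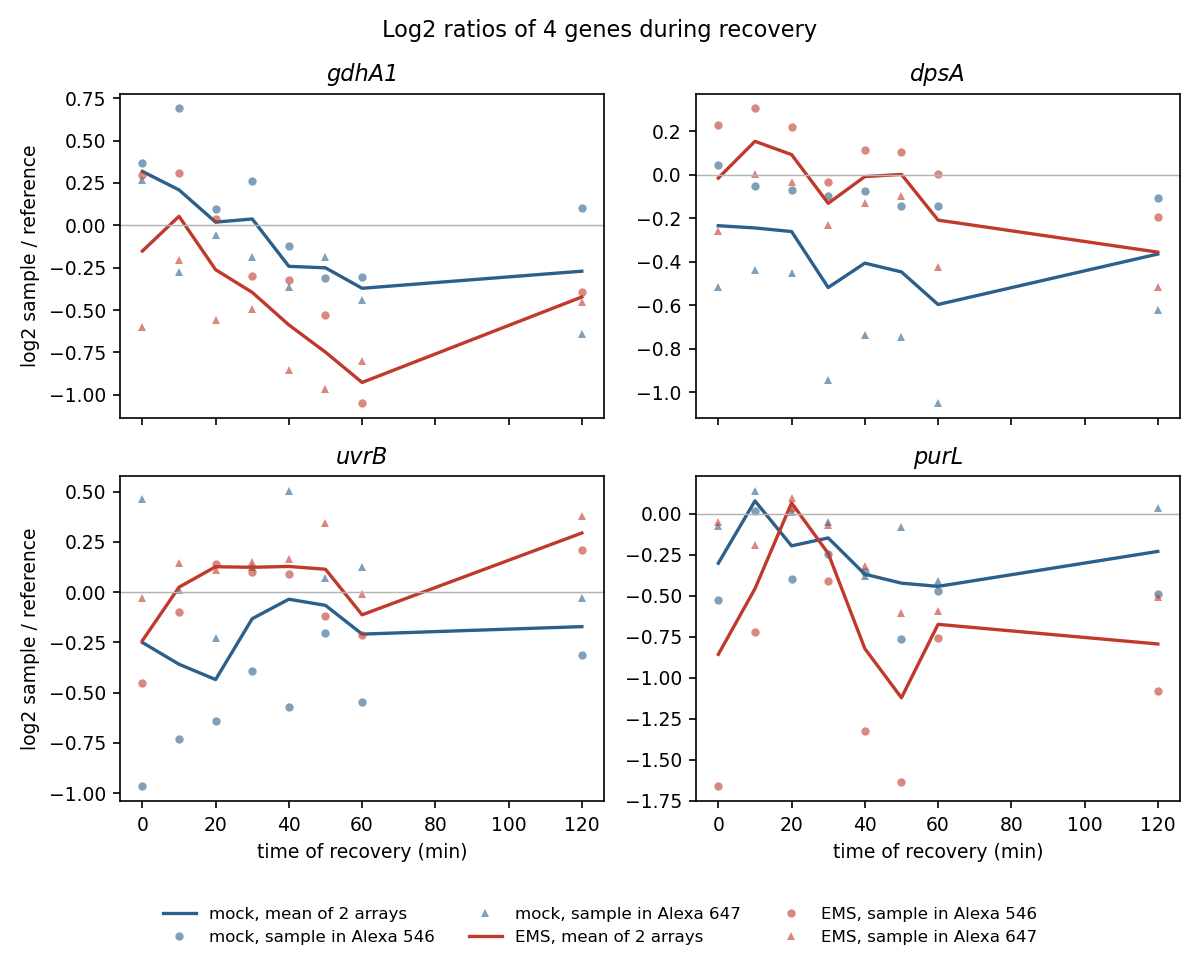
Log2 ratio of sample over reference (vertical axis) against time of recovery in min (horizontal axis) for gdhA1, dpsA, uvrB and purL. Lines join the means of the 2 arrays of each RNA sample. Circles are arrays with the sample in Alexa 546 and triangles arrays with it in Alexa 647. Lines and points are red for EMS and blue for mock. In EMS gdhA1 lay lower and dpsA higher at 8 of 8 time points, dpsA by 0.01 at 120 min.

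Among the named DNA repair genes, uvrB, which encodes the damage-binding subunit of the UvrABC excision nuclease, was the one bright enough to test. Other repair genes may be among the 877 tested probes without a name. The uvrB difference was 0.26 ± 0.07 (SE), positive at 8 of 8 time points, by 0.01 at 0 min. It did not pass over all probes (limma, adjusted p = 0.0937). As uvrB was the 1 tested member of nucleotide excision repair, adjustment over that list changes nothing, and its unadjusted p was under 0.05. The dye orientations differed, at 0.50 ± 0.09 (SE, adjusted p = 0.0323) with the sample in Alexa 546 and 0.03 ± 0.11 (SE, adjusted p = 0.971) with it in Alexa 647. It also passed with scaling between arrays (adjusted p = 0.0472) and with sample weights (adjusted p = 0.0422). The other subunit gene with a name here, uvrA, was above background in Alexa 546 on 13 of 32 arrays. It stood at 0.13 ± 0.11 (SE, adjusted p = 0.746) when the filter was dropped. The recombination gene radB, above background in Alexa 546 on 4 arrays, stood at 0.00 ± 0.07 (SE, adjusted p = 0.998) in that fit. The mismatch repair gene mutL, above background in that dye on 0 arrays, stood at 0.03 ± 0.09 (SE, adjusted p = 0.964). The list for base excision and direct reversal, the routes that remove alkylated bases, held 0 named genes here, so no value is given for it.

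Nucleotide biosynthesis had 7 tested genes, of which 0 passed over all probes, 5 had negative and 2 positive differences, and 1, purL, passed adjusted over the list alone. The purine synthesis gene purL stood at -0.36 ± 0.10 (SE), negative at 7 of 8 time points (limma, adjusted p = 0.0937), and purE of the same pathway at -0.15 ± 0.08 (SE). The purL difference passed with scaling between arrays (adjusted p = 0.0439), sample weights (adjusted p = 0.0108), a spline of time (adjusted p = 0.0355) and without 20 min (-0.45, adjusted p = 0.0111), and it was -0.54 in Alexa 546 and -0.18 in Alexa 647. The 2 subunit genes of aspartate carbamoyltransferase, which starts pyrimidine synthesis, stood at -0.10 ± 0.07 (pyrB, SE) and -0.14 ± 0.06 (pyrI, SE). The list had the smallest p of the 10 tested and did not pass (camera, p = 0.0229, adjusted p = 0.182; adjusted p = 0.557 with an estimated correlation). Tested against no change rather than against other genes, its members missed the threshold for a shift in 1 direction (fry, p = 0.0172, adjusted p = 0.172) and passed the test for change in either direction (fry, mixed, adjusted p = 0.0106).

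The 4 tested DNA replication genes had positive mean differences, with 0 passing over all probes and 1, gyrA, adjusted over the list alone. The DNA gyrase genes gyrA and gyrB stood at 0.27 ± 0.09 (SE, adjusted p = 0.132; 0.0374 with sample weights and 0.0400 without 0 min) and 0.26 ± 0.12 (SE, adjusted p = 0.309). The origin-binding protein genes orc8 and orc7 stood at 0.13 ± 0.13 (SE) and 0.02 ± 0.13 (SE), orc8 turning to -0.01 with no background correction and -0.15 in the authors' table. The positive sign held in Alexa 647 for 4 of 4 and in Alexa 546 for 2. In Alexa 546 and Alexa 647 the values were 0.47 and 0.08 for gyrA, -0.03 and 0.56 for gyrB, and -0.17 and 0.42 for orc8. Over all times the list did not pass (camera, adjusted p = 0.182). The 4 cobalamin synthesis genes had negative differences, led by the cobaltochelatase gene cobN at -0.20 ± 0.08 (SE, adjusted p = 0.240), and did not pass as a list either (camera, adjusted p = 0.182). All 5 tested tricarboxylic acid cycle genes had negative differences, from -0.16 ± 0.09 (SE) for malate dehydrogenase, mdh (adjusted p = 0.0449 with sample weights), to -0.01 ± 0.11 (SE) for sucC of succinyl-CoA synthetase (camera, adjusted p = 0.336). Of the 3 glutamate dehydrogenase genes, a list written after gene names were seen, gdhA1 passed. The gene gdhB stood at 0.24 ± 0.10 (SE, adjusted p = 0.305) and gdhA2 at -0.05 ± 0.14 (SE, adjusted p = 0.927). Both rest partly on 20 min, when the mock sample stood apart. The differences there were 0.90 for gdhB and -0.96 for gdhA2, against -0.21 to 0.38 and -0.62 to 0.38 at the other times. The gdhA2 difference was negative at 0 and 20 min and positive otherwise. At 20 min orc7 stood at -0.96 (-0.17 to 0.42 at other times), sucC at 0.78 (-0.32 to 0.29) and mdh at 0.42 (-0.40 to -0.05). Spots of gdhB were saturated in the high-gain scan on 32 arrays.

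Among 7 tested genes of the archaella and chemotaxis list, 4 had positive and 3 negative differences, from htr2, the transducer of sensory rhodopsin II, at 0.23 ± 0.08 (SE, adjusted p = 0.166; 0.0409 from the authors' values), to the response regulator gene cheY at -0.10 ± 0.07 (SE). The 11 named members of that list are all htr or che genes, so it gives no value for a named archaellum gene. The 8 aminoacyl-tRNA synthetase genes split 3 positive to 5 negative, with lysS at 0.09 ± 0.06 (SE) and ileS at -0.08 ± 0.08 (SE). Chaperones and proteasome held dnaK at -0.11 ± 0.07 (SE) and psmA, a proteasome subunit, at 0.07 ± 0.07 (SE). That list's median and mean were positive while camera's direction was down, and in coenzyme and heme biosynthesis the median was negative and the mean positive. These lists and protein export did not pass (camera, adjusted p from 0.618 to 0.878). In lists too small to test as such, the values were -0.06 ± 0.07 (SE) for the ribosomal protein gene rpl12p, 0.14 ± 0.07 (SE) for arcC and 0.13 ± 0.07 (SE) for arcA of arginine fermentation, 0.14 ± 0.08 (SE) for sop2, sensory rhodopsin II, and -0.04 ± 0.06 (SE) for nuoL and 0.01 ± 0.08 (SE) for sdhC of the respiratory chain. The orientations had opposite signs for sucC, gdhA2, cheY, lysS, psmA, rpl12p, nuoL and sdhC, and htr2 was 0.40 in Alexa 546 and 0.07 in Alexa 647. Of the 10 lists tested 0 passed with camera, and 1 had an unadjusted p under 0.05.

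Taken separately, neither the early nor the late part of recovery gave a gene that passed. In the window of 40 to 120 min the named gene with the smallest p was phoU, a regulator of phosphate uptake, at -0.43 ± 0.09 (SE) and negative at 4 of 4 time points. It averaged -0.85 ± 0.21 (SD, n = 4) in EMS and -0.42 ± 0.10 (SD, n = 4) in mock and missed the threshold (limma, adjusted p = 0.0600), at -0.71 in Alexa 546 and -0.15 in Alexa 647. In the same window purL stood at -0.49 ± 0.14 (SE, adjusted p = 0.149), gdhA1 at -0.39 ± 0.10 (SE, adjusted p = 0.119), the serine hydroxymethyltransferase gene glyA at -0.36 ± 0.10 (SE, adjusted p = 0.153) and gyrB at 0.47 ± 0.14 (SE, adjusted p = 0.187). In Alexa 546 and Alexa 647 the values were 0.06 and 0.87 (adjusted p = 0.0153) for gyrB, -0.60 and -0.12 for glyA, and -0.68 and -0.30 for purL. From 0 to 30 min dpsA stood at 0.34 ± 0.10 (SE, adjusted p = 0.168), gdhA1 at -0.33 ± 0.10 (SE, adjusted p = 0.190) and uvrB at 0.30 ± 0.11 (SE, adjusted p = 0.259), the last from 0.60 in Alexa 546 and 0.00 in Alexa 647. By limma, 0 probes passed at 0 to 30 min (137 at an unadjusted p under 0.05) and 0 at 40 to 120 min (127 at that p). The late count was 16 without 20 min, 6 without 120 min and 1 without 10 min. With sample weights 8 passed early and 96 late, in the array-level fit 24 and 24, with scaling between arrays 10 and 8, and with the sample in Alexa 647 alone 0 and 29.

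The gene lists were tested in these windows too, as a comparison added after the data were seen. At 40 to 120 min DNA replication passed, with 4 of 4 genes higher in EMS and a median difference of 0.33 (camera, p = 0.00385, adjusted p = 0.0385), and 1 of them passed adjusted over the list alone. It passed in 1 of the dye orientations, with a median of 0.56 in Alexa 647 (adjusted p = 0.0390) and 0.08 in Alexa 546 (adjusted p = 0.366). It did not pass with an estimated correlation (adjusted p = 0.368) or with fry (adjusted p = 0.139), nor without 50 min (adjusted p = 0.0605) or 120 min (adjusted p = 0.0810). With the group of arrays as a covariate its median was 0.15 (adjusted p = 0.624), and it was also 0.15 from the authors' values (adjusted p = 0.448). Over 22 alternatives the call held in 9. From 0 to 30 min 0 of 10 lists passed with camera, and 1, nucleotide biosynthesis, had an unadjusted p under 0.05 (p = 0.0460).

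The change of the EMS minus mock difference between the windows was tested directly, and 0 probes passed in limma, with 100 at an unadjusted p under 0.05. Its smallest p among named genes was that of phoU, at -0.56 ± 0.13 (SE, adjusted p = 0.272), followed by htr1, the transducer of sensory rhodopsin I, at -0.65 ± 0.18 (SE, adjusted p = 0.359). The change was -0.05 ± 0.14 (SE, adjusted p = 0.904) for gdhA1 and -0.03 ± 0.13 (SE, adjusted p = 0.957) for dpsA. Of the 10 gene lists 0 changed between the windows, with 1 at an unadjusted p under 0.05, DNA replication (camera, p = 0.0238, adjusted p = 0.238).

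Within mock-treated cells, 40 to 120 min was set against 0 to 30 min to show what recovery itself did. The 1 probe that changed was unnamed probe 5053, which fell by 1.21 ± 0.15 (SE), from 0.26 ± 0.34 (SD, n = 4) to -0.94 ± 0.09 (SD, n = 4) (limma, adjusted p = 0.000459). Among named genes gdhA1 stood at -0.43 ± 0.12 (SE, adjusted p = 0.0698), the agmatinase gene speB at 0.37 ± 0.11 (SE, adjusted p = 0.0940) and the aspartate-semialdehyde dehydrogenase gene asd at 0.27 ± 0.08 (SE, adjusted p = 0.106). The 7 tested genes of the archaella and chemotaxis list had positive differences, and the list did not pass (camera, p = 0.0786, adjusted p = 0.591). Of these genes 7 were positive in Alexa 546 and 4 in Alexa 647. The early window holds the 20 min sample, which stood apart from the other mock samples. In it all 7 genes deviated downwards from the mean of the other mock samples, from -0.97 for htr1 to -0.09 for cheA. The positive signs thus rest in part on that sample. Of the 10 lists 0 passed and 0 had an unadjusted p under 0.05. At an unadjusted p under 0.05 there were 182 probes, and the count that passed was 63 without 30 min. It was 163 with sample weights, 25 in the array-level fit and for a linear trend in time rank, 24 from the authors' values and 19 with no background correction. From the first print set of the authors' values alone the count was 1. In the second print set, 3 late mock arrays hold a corner where the authors' values disagree with the scanner values. With sample weights gdhA1 (-0.52, adjusted p = 0.00220), arcC (0.85, adjusted p = 0.00124), speB (0.33, adjusted p = 0.0182) and asd (0.30, adjusted p = 0.00984) were among those that passed.

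Within EMS-treated cells the same comparison gave 24 probes, 10 that rose and 14 that fell. The named gene among them was gdhA1, which fell by 0.48 ± 0.12 (SE), from -0.19 ± 0.19 (SD, n = 4) at 0 to 30 min to -0.67 ± 0.22 (SD, n = 4) at 40 to 120 min (limma, adjusted p = 0.0354). Of the unnamed probes, 3141 rose by 0.92 ± 0.13 (SE) and 2733 by 0.89 ± 0.16 (SE), while 5053 fell by 1.13 ± 0.15 (SE) and 1605 by 1.12 ± 0.21 (SE). Named genes that missed the threshold included csg, the cell surface glycoprotein of the S-layer, at -0.37 ± 0.10 (SE), the translation initiation factor gene infB at 0.42 ± 0.12 (SE) and the cytidylate kinase gene cmk at 0.39 ± 0.11 (SE), with an adjusted p of 0.0579 each. Spots of csg were saturated in the high-gain scan on 32 arrays and in the low-gain scan on 12, so its value is not settled. The infB value was 0.02 in Alexa 546 and 0.81 in Alexa 647 (adjusted p = 0.00969), and that of gdhA1 -0.66 and -0.30. The glutamine synthetase gene glnA stood at -0.44 ± 0.14 (SE, adjusted p = 0.0730). The 4 DNA replication genes had positive mean differences, 2 of them negative in Alexa 546, with 2 passing adjusted over the list alone, as did 7 of 8 aminoacyl-tRNA synthetase genes, with 0 passing. Neither list passed (camera, adjusted p = 0.538 each), and of the 10 lists 0 passed and 0 had an unadjusted p under 0.05. That gdhA1 passed in EMS and not in mock does not show that its courses differed, since the test of that change passed for 0 probes. With the group of arrays as a covariate 0 probes passed (171 at an unadjusted p under 0.05 without it), and gdhA1 stood at -0.44 ± 0.17 (SE, adjusted p = 0.676). The EMS samples of the other group of arrays are those of 60 and 120 min and, in 1 of its arrays, 50 min, so it holds no early sample to compare within it. The count was 8 without 0 min, 2 without 10 or 60 min, 67 without 20 min, 5 without 50 min and 11 without 120 min. It was 0 for a linear trend in minutes, 4 with the sample in Alexa 546 alone, 53 with it in Alexa 647 alone and 132 with sample weights. The gdhA1 call was lost without 0, 10, 50 or 60 min.

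At single time points there was 1 RNA sample per treatment, so the differences carry no test. The median size of the EMS minus mock difference over 955 probes was 0.32 at 20 min and between 0.13 and 0.20 at the other 7 times. Probes that differed by at least 1 in size, with the same sign on both arrays, numbered 47 at 20 min, 12 higher and 35 lower in EMS. There were 20 at 120 min, 18 higher and 2 lower, and between 0 and 4 at the other 6 times. The 20 min difference moved with the mock sample of that time, in which serS, for seryl-tRNA synthetase, deviated from the mean of the other 7 mock samples by -1.17 and ppsA, for phosphoenolpyruvate synthase, by -1.15.

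**Figure D2:**
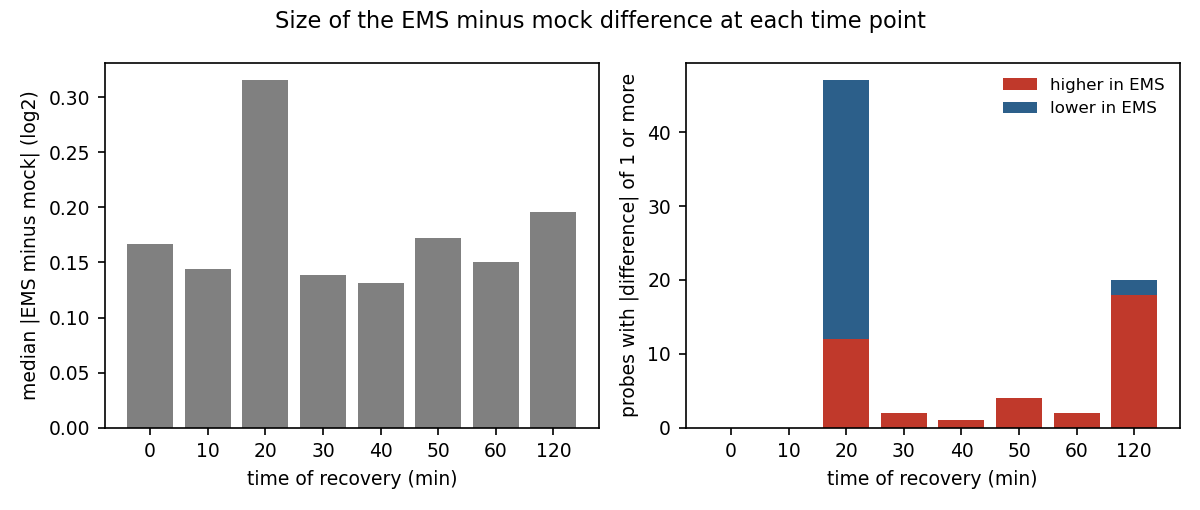
Left, median size of the EMS minus mock log2 difference over 955 probes at each time of recovery in min. Right, number of probes that differed by 1 or more on the log2 scale at each time, higher (red) or lower (blue) in EMS; 20 min, with a median of 0.32 and 47 probes, stands above the other times.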

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

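Of the tests in this part, the comparison of the mock 20 min arrays with each other and the test for an exchange of samples were chosen only after the result was seen.

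In 93 groups of 8 values, 8 held a sample far from the others by Dixon's test, where chance gives 4.65. In the EMS group the arginine deiminase gene arcA stood at -0.58 in the 0 min sample, against 0.15 to 0.51 in the other 7. In mock arcA was lowest at 0 min too, at -0.38 against -0.18 to 0.29 at the other times. The proteasome gene psmA stood at 0.36 in the EMS 0 min sample, against -0.13 to 0.03 in the other EMS samples. The 2 arrays of that EMS sample correlated across probes with r = 0.125, the lowest of the 16 samples. The chemotaxis kinase gene cheA stood at -0.21 in the EMS 20 min sample, against -0.55 to -0.44 in the others. The transducer gene htr8 stood at 0.14 in the EMS 120 min sample, against -0.16 to -0.03 in the others.

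The mock 20 min sample stood apart in 3 of the 8. Its value on the first principal component, which holds 35.0% of the variance, was 14.4, against -3.95 to -0.69 in the other mock samples. The spread of its log2 ratios over probes was 0.749 (SD), against 0.353 to 0.487. The origin-binding gene orc7 stood at 1.57, against 0.20 to 0.78. Across probes its deviation correlated with r = 0.413 with that of the EMS 120 min sample from the other EMS samples, which had the next highest first component, 4.51. A 4th group far from the others is the EMS minus mock difference at 20 min, of median size 0.32 against 0.13 to 0.20 at the other times, which fell to 0.21 with scaling between arrays.

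In this sample the seryl-tRNA synthetase gene serS deviated from the mean of the other mock samples by -1.17, the phosphoenolpyruvate synthase gene ppsA by -1.15 and the thiamine synthesis gene thiC by -0.98, while orc7 deviated by 1.19 and the glutamate dehydrogenase gene gdhA2 by 0.90. A fault of 1 array is argued against, since the deviations on its 2 arrays correlated across probes with r = 0.838. An exchange with the EMS sample of 20 min cannot be judged by distance, since a sample apart from all others lies far from either group. This sample lay 0.500 (root mean square) from the mean of the 7 EMS samples of other times. That is 1.64 times as far as the farthest of those 7 lay from the mean of the rest (0.305). From the mean of the other mock samples it lay 0.537. A trend of the ratio with signal brightness cannot be judged here, since the loess step is made to remove such a trend before this test. The Spearman correlation across probes was -0.028. A change in the RNA or the culture of this sample may remain as the source, and no biological explanation was tested, since the labels give this sample no other condition.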

How the results depend on the processing

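The scan gain, the Alexa 647 filter, the first print set, the term for groups of arrays, 0 to 40 min alone, the omission of mock 20 min, the lists in the early and late windows or with single dyes and every value for both treatments together were chosen only after the results were seen. Counts of passing probes are given over all times (20), early (0), late (0), in the mock course (1), in the EMS course (24) and in both treatments together (91). Except where a cause is named, the cause was not tested.

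With no background correction there were 7 late and 19 in the mock course. Median centring gave 9 late and 39 in the EMS course, and over all times 12 higher and 8 lower, against 15 and 5. Scaling between arrays gave 51 over all times, 10 early, 8 late, 3 in the mock course and 10 in the EMS course, of which 6 rose and 4 fell, against 10 and 14. Without the filter, with 2400 probes tested, there were 6 over all times and 11 in the EMS course. The authors' value table gave 11 late, 24 in the mock course and 151 for both treatments. Its first print set alone gave 10 over all times, 1 late, 1 in the mock course, 9 in the EMS course and 91 for both. The second print set holds the corner, described below, where the table disagrees with the scanner values on 3 late mock arrays. The sample in Alexa 647 alone gave 13 over all times, 29 late, 53 in the EMS course and 43 for both treatments. Alexa 546 alone gave 11 over all times, 1 early, 11 in the mock course, 4 in the EMS course and 37 for both. The array-level fit gave 41 over all times, 24 early, 24 late, 25 in the mock course and 60 in the EMS course. Sample weights gave 72, 8, 96, 163, 132 and 264 in the order above.

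Over all times, the median over spots gave 12, no time block 5, a spline of time 35, the high-gain scan 13 and the low-gain scan 6. The low-gain scan gave 1 early and 5 in the mock course. A linear trend in minutes gave 0 in each course, and one in time rank 25 in mock and 45 in EMS. The Alexa 647 filter gave 11 in the EMS course. The term for groups of arrays gave 3 over all times, 0 in the EMS course and 10 for both. Time points 0 to 40 min gave 0 over all times. Of the 56 choices of 5 time points, 30 gave 0 and the highest gave 61, so fewer samples alone can give 0. Without mock 20 min there were 105 in the EMS course and 164 for both, with the 24 and the 91 among them. In the EMS course the estimates cannot change with a mock sample (gdhA1 stays at -0.48), so the error shared by the fit fell.

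Leaving out 1 time point gave 5 to 34 over all times (11 without 10, 34 without 20, 5 without 30, 50 or 60 and 6 without 40 min) and 0 to 16 late (1 without 10, 16 without 20 and 6 without 120 min). It gave 1 to 63 in the mock course (63 without 30 min) and 2 to 67 in the EMS course (8 without 0, 2 without 10 or 60, 67 without 20, 5 without 50 and 11 without 120 min). For both treatments it gave 17 to 126 (17 without 10, 41 without 40, 26 without 50 and 18 without 60 min).

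The change between windows stayed at 0 in 26 alternatives. List counts of 0 became 1, nucleotide biosynthesis, over all times and early without the filter, and over all times and in each course with the Alexa 647 filter. They stayed at 0 in the other alternatives, with estimated correlations and one-way fry among them. The late count of 1, DNA replication, became 0 with no background correction, median centring, scaling, the value table or its first print set, estimated correlations, one-way fry, Alexa 546 alone and either scan alone. It ran from 0 to 1 with a time point left out, at 0 without 50 min. Without 120 min, and with the term for groups of arrays, the 1 that passed was cobalamin biosynthesis instead (adjusted p = 0.0181 and 0.0267). The call of DNA replication held in 9 of 22 alternatives (adjusted p from 0.0185 to 0.624). Lists were not tested with the array-level fit, sample weights or the median over spots.

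Among named genes csg turned from -0.31 for both treatments to 0.044 in the value table and 0.012 in its first print set. Of 4386 recomputed gene values, 4157 kept their side of the threshold, 78 gained a call, 149 lost one and 2, those of csg, reversed. Most of the 4386 belong to genes that did not pass in the main fit, so the share kept says little about the calls. The 149 lost and the 2 reversed all come from values that passed there. A further 331 values without a call had the other sign. Over 26 alternatives gdhA1 kept its sign in 26 (-0.39 to -0.19, adjusted p from 0.00355 to 0.231) and its call in 14, and dpsA its sign in 26 (0.00 to 0.48, adjusted p from 0.00287 to 0.991) and its call in 10. In the EMS course gdhA1 kept its call in 12 of 26. The median size of the difference per time point stayed within its spread in 4 of 4 alternatives (0.120 to 0.191). Signal over background in Alexa 546 limits which genes could be tested.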

Other observations

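Of the tests in this part, the comparison of both treatments together, the comparison samples for the groups of arrays, the tests of the authors' table, and the splits for the early window, the late window, the change between windows and the gene lists, and the comparison of estimates and errors under the covariate, were chosen only after results were seen.

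Over both treatments, 10 named genes differed between 0 to 30 min and 40 to 120 min, and 5 of them fell. The glutamate dehydrogenase gene gdhA1 fell by 0.46 ± 0.08 (SE), from -0.02 ± 0.24 to -0.48 ± 0.25 (SD, n = 8 each; limma, adjusted p = 0.00222). The glutamine synthetase gene glnA fell by 0.35 ± 0.10 (SE, adjusted p = 0.0305), and of 7 tested nucleotide biosynthesis genes 2 fell, purE by 0.29 ± 0.08 (SE, adjusted p = 0.0366) and purL by 0.35 ± 0.11 (SE, adjusted p = 0.0484). That list as a whole did not pass (camera, p = 0.158). The surface glycoprotein gene csg, at -0.31 ± 0.07 (SE, adjusted p = 0.0157), was saturated in the high-gain scan on 32 arrays and in the low-gain scan on 12, and stood at 0.044 in the authors' value table, so its fall is not settled.

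The other 5 rose. The carbamate kinase gene arcC, the last step of arginine fermentation, rose by 0.59 ± 0.15 (SE), from 0.01 ± 0.44 to 0.60 ± 0.12 (SD, n = 8 each; limma, adjusted p = 0.0208). The agmatinase gene speB rose by 0.32 ± 0.08 (SE, adjusted p = 0.0183), the aspartate-semialdehyde dehydrogenase gene asd by 0.24 ± 0.06 (SE, adjusted p = 0.0183), the initiation factor gene infB by 0.29 ± 0.08 (SE, adjusted p = 0.0385) and the transducer gene htr2 by 0.25 ± 0.08 (SE, adjusted p = 0.0484). The infB rise is not settled, at 0.033 (adjusted p = 0.922) in Alexa 546, 0.54 in Alexa 647 and 0.041 (adjusted p = 0.689) from the authors' values, and arcC was 0.35 and 0.83 in the orientations. In all 91 of 955 probes passed, 49 that rose and 42 that fell. The count was 17 without 10 min, 41 without 40 min, 26 without 50 min and 18 without 60 min. All 91 had the same sign in both dye orientations, as did 72.6% of all 955 probes (r = 0.694 between orientations). With the group of arrays as a covariate 10 passed, none of them among these 10 named genes, and gdhA1 then stood at -0.44 (adjusted p = 0.0524). The estimates of the 91 probes kept their sign in 91 and came to a median of 0.968 times, and their errors to 1.28 times, those without it. Over 24 alternatives the calls of gdhA1 held in 22, arcC in 18, speB in 17, asd in 15, csg in 14, glnA in 13, purE in 11, htr2 in 9, purL in 7 and infB in 5. Across probes, which are not independent replicates, the change in EMS correlated with that in mock with r = 0.396 (Spearman 0.320), and 61.8% of probes moved the same way.

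Other splits of the samples bear on whether chance gave these counts. For EMS against mock over all times, 1 of 100 exchanges of labels within time points, the real one, gave as many as 20 probes, and the highest other gave 4. For the EMS course 1 of 35 splits of the times, the real one, gave as many as 24, with a highest other of 1. For both treatments 1 of 35 gave 91, with a highest other of 1. Other groupings of these samples thus rarely gave such counts in these 3 comparisons. The real split of the times is the one that keeps them in order, so a slow drift would single it out too. Chance differences between cultures are not excluded, since the samples of a treatment may come from 1 culture. Nor is an effect of array order excluded. The 16 mock arrays are numbered before the first EMS array and the numbers follow time within each treatment. Such an effect cannot be told from treatment or time by these splits. For the mock course 2 of 35 splits gave 1 probe, so a chance split is not excluded there. For the change between windows, with 0 probes, all 35 gave as many and the highest other was 0. The early and late windows allow 8 exchanges each, too few for a share under 0.05. All 8 gave 0 probes in each window and 0 lists early, and 3 of the 8 gave as many late lists as the real 1. For the other lists, with 0 passing, 100 of 100 exchanges over all times and 35 of 35 splits for the change between windows and for each course gave as many, with a highest other of 2 over all times and 1 in the others.

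The 24 probes that changed with time in EMS raise the question of the groups of arrays, since 5 arrays of the EMS samples of 50, 60 and 120 min form a group of their own, with 1 of the 2 EMS 50 min arrays in each group. Over the 24 probes, the difference of the EMS 50 min arrays, less the usual dye difference, correlated with the change over time computed without that sample with r = 0.748, above the 0.5 set beforehand for an effect of the group. The same value in 7 samples whose arrays share a group ran from -0.702 to 0.612, so it is too noisy to decide, and the arrays of another group and a response to EMS cannot be told apart. With the group as a covariate gdhA1 moved from -0.48 ± 0.12 to -0.44 ± 0.17 (SE) and 0 probes passed. Over the 24 probes the estimates came to a median of 0.859 times and the errors to 1.48 times their size without it, so a smaller change and larger errors are not separated as the source of the loss.

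On 3 mock arrays, 1 each of the 50, 60 and 120 min samples, scanner ratios and the authors' table disagree in 1 corner of 1792 spots, with r from -0.004 to 0.048 there and at least 0.847 elsewhere. Misplaced spots in the scanner files are argued against, since spots of 1 probe in the 2 print sets correlated there with r of at least 0.820. In the authors' table they correlated with r of at most 0.202, which is consistent with misplaced spots in the table. On the other 29 arrays r in that corner ran from 0.503 to 0.993. The lowest, 0.503 and 0.589, were those of the other mock 60 and 50 min arrays, against 0.960 and 0.965 elsewhere on them. The limit of 0.5 that set the 3 arrays apart thus leaves milder disagreement on others. The scanner values were used for the results above.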
